A study of Mus musculus with 6 samples.

How the data were processed

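RNA of sorted MC38 cells from 3 PBS-treated and 3 DT-treated samples was measured on Illumina mouse bead arrays. Per the labels' protocols, cells were isolated from tumour-bearing livers by fluorescence-activated sorting, total RNA was extracted with Trizol and its quality checked, and it was amplified with an oligo-dT based Illumina kit and labelled with biotin, in a single colour. The sort gate, the scanner, its software and the normalization of the deposited values are not given in the sources used here. The deposited values are of 3 kinds. Per the file headers, the authors deposited a mean bead signal per probe and array, an intensity that the values show to be linear, not background-subtracted and not normalized between arrays. Beside it stands a deposited detection p-value per probe and array, which moves in equal steps from 0 to 1. The authors also deposited a normalized log2 value per probe. These log2 values keep the order of the signals within each array, with a Spearman correlation of at least 0.999998, have medians of 4.786, 4.953, 4.836 in PBS and 4.878, 4.754, 4.806 in DT, and are not centred per gene. How they were made is unknown, and they served as an alternative only. All columns matched a labelled sample.

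Gene names came from the platform's annotation, with symbols updated through Entrez identifiers for 34807 probes and kept as given for 96. Of the 45281 probes, 34885 had 1 gene, 18 several genes and 10378 no gene named here, and probes with several genes or none were left out of tests by gene. No genome was used, and no coordinates are printed. Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which estimates background from the detection p-values by normexp, adds an offset of 16, applies quantile normalization and takes log2. The offset shrinks fold changes of dim genes, and the quantile step removes any change shared by all genes. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 17759, of which 14903 had 1 gene. For each gene, the probe with the highest mean over all arrays was used, giving 9483 genes. Of 3691 genes with several probes, 2132 had the same sign in all of them, and of 25 such genes past the threshold 20 did, the exceptions being Arpp19, Enah, Parp9, Ssbp2 and Vav3.

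DT was compared with PBS by lmFit and eBayes, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All tests were two-sided, and fold changes are DT over PBS on the log2 scale. A gene not above background on every array of a group has only a bound there. It is given as at least N-fold, from the mean of the brighter group against, per dim array, the higher of the gene's own value and the lowest value among probes above background. With 3 arrays against 3, an exact permutation test of a single value cannot give a p below 0.1, so that calls rest on the spread shared across genes in limma. Of 33 gene lists, 30 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. All 7 calls were lost with an estimated correlation. In fry, 0 lists passed for movement on balance one way and 12 for change in either direction.

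Correlations between arrays, over genes, were from 0.9786 to 0.989 within PBS, from 0.986 to 0.9871 within DT and from 0.9608 to 0.9856 between the groups. The first principal component held 49.56% of the variance and put the PBS arrays at −15.1, −21.3 and −17.2 and the DT arrays at 20.4, 28.7 and 4.52. Mean signals were 473.1, 311.3 and 449.2 in PBS and 363.1, 503.1 and 436.4 in DT.

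Groups, lists, tests, alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names Angptl7 and the other angiopoietin-like genes. It also names the 12 genes with the largest rises and the 12 with the largest falls among those past the threshold without overlap of the groups, leaving out clone-type identifiers. Of each list it names the 2 members with the smallest p, or 4 where the list passed. Alternatives covered background correction, normalization, the deposited normalized values, the filter, the replicate number as a block, an intensity trend, array weights, every probe tested, an adjusted p under 0.1, an unmoderated test, other list tests and leaving out each array. The procedure was tested on simulated data for DT against PBS with 11583 genes, where it recovered 0 of 64 genes changed by 0.5 on the log2 scale, 34 of 59 (57.6%) changed by 1 and 51 of 55 (92.7%) changed by 2. Of 89 calls there, 4 were unchanged genes. Figures were drawn with matplotlib 3.10.9.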

Results

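Gene expression was measured in mouse MC38 colon carcinoma cells that had been sorted out of tumour-bearing livers. The cells had been injected into the spleen, from where they seed metastases in the liver, of mice carrying the CD11b-DTR transgene. In these mice, diphtheria toxin (DT) is meant to kill cells that use the CD11b promoter. That promoter is active in macrophages, monocytes, neutrophils and other myeloid cells, and which of these DT removed was not measured here. Mice received PBS or DT by intraperitoneal injection on days 7 and 9, and livers were collected on day 10. The comparison of 3 DT samples with 3 PBS samples asks how the transcripts of the tumour cells differ after DT, given to deplete myeloid cells. Angptl7, named in the title of the series, is its first gene of interest. Each sample was hybridised to 1 Illumina bead array, whose median signal lay between 135 and 153.8 and on which between 36.7% and 40.62% of the 45281 probes lay above background. The number of arrays limits the precision. The labels do not state whether the 3 samples of a group came from separate mice or pools, so that p-values measure the spread between these samples, which may be technical.

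Angptl7, which encodes a secreted angiopoietin-like protein, showed the largest rise after DT of all the genes named here. Its normalized log2 signal was 6.72 ± 0.57 (SD, n = 3) in PBS and 9.33 ± 1.16 (SD, n = 3) in DT, a 6.10-fold difference, or 2.61 on the log2 scale (SE 0.49; limma, adjusted p = 0.0459). Before normalization, the probe (ILMN_2844820) gave signals of 321.5, 178.4 and 201.4 in the PBS samples and of 676.4, 1916 and 404.8 in the DT samples. A second Angptl7 probe went from 5.28 ± 0.35 to 7.15 ± 0.92 (SD), a rise of 1.87 (adjusted p = 0.0473 with limma over every probe), and lay above background on 2 of the 3 PBS arrays. Of the other angiopoietin-like genes measured, Angptl4 gave 0.53 (SE 0.35) and Angptl6 gave −0.36 (SE 0.17), with adjusted p-values of 0.381 and 0.219 in limma. Angptl1 and Angptl8 were not above background on any array. The angiopoietin and angiopoietin-like list, with 5 measured genes and a median of 0.24, did not pass the list test (camera adjusted p = 0.293), and Angptl7 was also its 1 gene past the threshold when adjusted over the list alone. The call for Angptl7 was lost without PBS replicate 2 (adjusted p = 0.0731), PBS replicate 3 (0.0702), DT replicate 1 (0.159) or DT replicate 2 (0.207), with rises between 2.07 and 3.23 over all arrays left out in turn. With each array's mean of the macrophage markers as a covariate, an alternative added after the data were seen, the rise was 3.025 (SE 0.70, adjusted p = 0.347 in limma), and the call was also lost with no filter on dim probes (adjusted p = 0.118) and in an unmoderated linear model (adjusted p = 0.243).

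**Figure D1:**
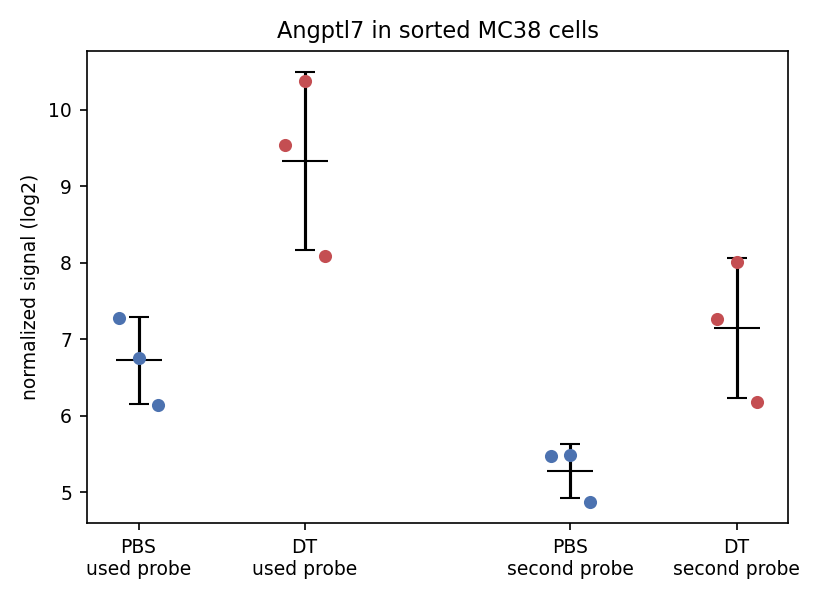
Normalized log2 signal (y axis) of the Angptl7 probe used in the test and of the second Angptl7 probe in sorted MC38 cells of the PBS and DT groups (x axis), with each array as a point and the mean ± SD (n = 3) as bars. In both probes the 3 DT values lie above the 3 PBS values, and the used probe has group means of 6.72 and 9.33.

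Among genes past the threshold, the largest rises after that of Angptl7 were in S100a8, Islr and Omd. S100a8, a calcium-binding protein abundant in neutrophils, rose by 2.18 on the log2 scale, and the secreted lipocalin Lcn2 and the resistin-like Retnlg were at least 2.77-fold and at least 2.08-fold higher, since neither lay above background on any PBS array. Islr (2.18) and the small leucine-rich proteoglycans Omd (1.88) and Aspn (at least 2.44-fold higher, not above background on any PBS array) rose with Dpt, an extracellular matrix protein (1.74). So did the eosinophil chemoattractant Ccl11 (1.63), the laminin chain Lama2 (1.59), the collagen V chain Col5a2 (1.58) and the angiotensin-converting enzyme Ace (1.57). Dpt was the tightest of them, at 6.48 ± 0.0041 in PBS and 8.23 ± 0.30 in DT (SD, n = 3; limma, adjusted p = 0.00671). Islr lay above background on 2 and Lama2 on 1 of the 3 PBS arrays. Within the DT group, replicate 2 was highest and replicate 3 lowest for Angptl7, Islr, Omd, Aspn, Dpt and Ccl11. This order does not set these genes apart: Lama2, Ace and the first principal component over all genes had it too. In S100a8, Lcn2 and Retnlg, DT replicate 1 was highest. Markers of stellate cells and fibroblasts, which did not pass as a list, had a median of 0.21 beside these rises.

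The deepest falls among the named genes were in Dbp, a transcription factor driven by the circadian clock (−2.09), the scaffold protein Grip1 (−2.01) and the inducible heat shock chaperone Hspa1a (−1.93). Dbp fell from 9.63 ± 0.34 to 7.54 ± 0.50 and Grip1 from 7.00 ± 0.19 to 4.997 ± 0.33 (SD, n = 3), with adjusted p-values of 0.0193 and 0.00671 in limma, and Grip1 lay above background on 1 of the 3 DT arrays. Nr1d1, another output gene of the clock, is outside the 12 largest falls and was added to this text after its values were seen: it fell by 1.15 (SE 0.21). The histone genes H2ac6 (−1.93), H2bc3 (−1.54) and H2bc18 (−1.42) fell, with the reservation that near-identical histone genes can share a probe. H2-Ab1 (−1.65) and H2-Eb1 (−1.53), which encode chains of MHC class II molecules, fell as well. The list ends with the cell adhesion protein Igsf9 (−1.69, above background on 1 of the 3 DT arrays), the protease inhibitor Spint1 (−1.43), the autophagy protein Atg9b (−1.42) and the ubiquitin ligase Rnf213 (−1.42).

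**Figure D2:**
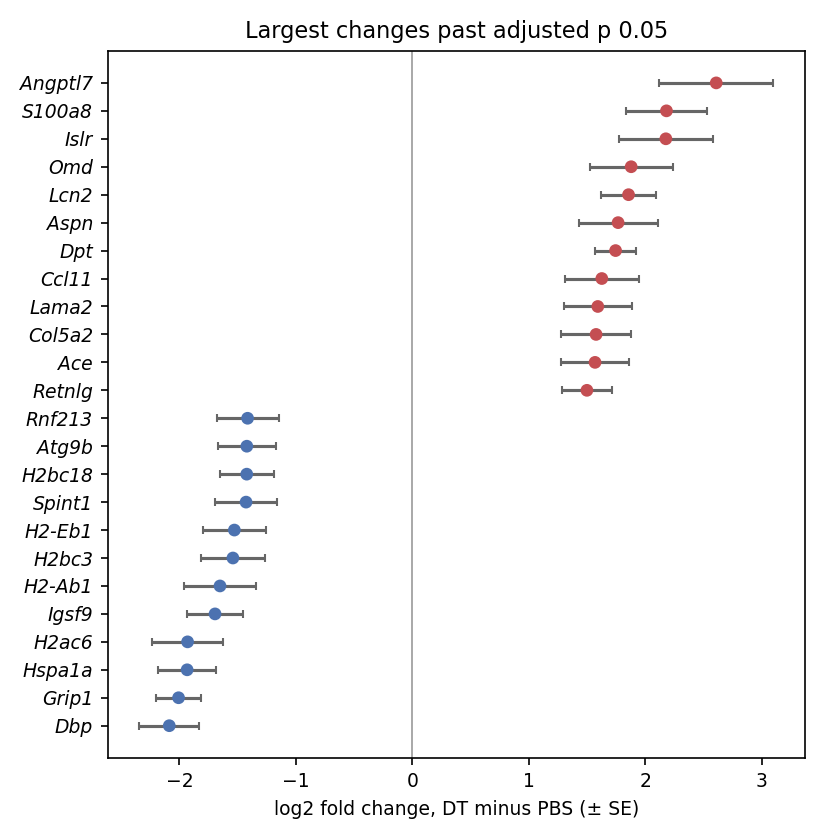
Log2 fold change (x axis, DT minus PBS) with its standard error from limma for the 12 genes with the largest rises (red) and the 12 with the largest falls (blue). All are past an adjusted p of 0.05, and clone-type identifiers were left out, among them the deepest fall past the threshold (−2.17). The points run from 2.61 for Angptl7 to −2.09 for Dbp.

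Over the whole array, 103 of 9483 genes tested passed an adjusted p of 0.05 in limma, of which 31 were higher and 72 lower in DT. Among them 68 differed by more than 2-fold, 19 higher and 49 lower, and in all 103 the 3 DT values lay on one side of the 3 PBS values. Such separation held for 2744 genes, or 28.9% of those tested, where chance gives 10%. An unadjusted p under 0.05 was reached by 2266 genes, where 474 are expected with no difference. Scaling of each array to a common median, without the quantile step, called 27 genes, 20 higher and 7 lower, with a median over all genes of 0.165 on the log2 scale against 0.011. The deposited normalized values called 313 genes, 151 higher and 162 lower. The count was 63 without PBS replicate 1, 3 without PBS replicate 2, 4 without DT replicate 1, 389 without DT replicate 3 and 0 without DT replicate 2, where 1299 genes had an unadjusted p under 0.05 in limma. It was 30 with the replicate number as a block and 0 with the macrophage covariate, where 981 genes had an unadjusted p under 0.05. That covariate lay below its PBS mean on every DT array, and within the groups it varied mostly through PBS replicate 3. It also leaves fewer residual degrees of freedom. The loss of calls therefore cannot show that macrophage content accounts for the changes.

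Macrophage and monocyte markers were lower in DT as a group: 15 of 16 measured genes had a negative fold change, with a median of −0.88 (camera adjusted p = 2.06e-05). The list's adjusted p = 0.806 with an estimated correlation. The median was −0.62 with a normexp offset of 50 and −0.46 without background correction. With no filter on dim probes it was −0.51 over the 25 genes with a probe, and the list passed (camera adjusted p = 6.66e-05). None of its genes passed over all genes in limma, 11 had an unadjusted p under 0.05, and 9 were lower when adjusted over the list alone. The lysosomal membrane protein Laptm5 gave −1.36 (SE 0.33), the complement components C1qb and C1qa −1.10 (SE 0.27) and −1.004 (SE 0.30), and Aif1, an actin-binding protein of macrophages, −1.29 (SE 0.32), with adjusted p-values from 0.0601 to 0.0972 in limma. Relative to the PBS mean, the mean of the list stood at 0.33, 0.36 and −0.69 in PBS replicates 1 to 3 and at −0.80, −0.82 and −0.66 in DT replicates 1 to 3, so that PBS replicate 3 lay at the level of the DT arrays.

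The dendritic cell and MHC class II list fell with a median of −1.20 over 9 measured genes (camera adjusted p = 0.000996; adjusted p = 0.806 with an estimated correlation). With no filter on dim probes the median was −0.12 over 16 genes, so that its size rests on the filter, and the list passed (camera adjusted p = 0.00687). The size rests on the background step too, with −0.72 at a normexp offset of 50 and −0.51 without background correction. H2-Ab1 and H2-Eb1 fell, 7 genes did not pass, and 5 were lower when adjusted over the list alone. H2-Aa, the partner chain of H2-Ab1, gave −1.28 (SE 0.31), and Cd74, the invariant chain that accompanies MHC class II molecules, −1.48 (SE 0.37). Their adjusted p-values in limma were 0.06 and 0.0647. PBS replicate 3 stood nearer to the DT arrays here too, at −0.48 against 0.16 and 0.32 in the other PBS arrays and −0.98, −1.004 and −0.66 in DT.

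Neutrophil markers rose with a median of 0.87 over 11 measured genes (camera adjusted p = 0.00518; adjusted p = 0.806 with an estimated correlation). The size of the median rests on the filter: it was 0.23 over 20 genes with no filter (adjusted p = 0.00719) and 1.498 with a detection p under 0.01 (adjusted p = 0.000137). It rests on the background step too, with 0.55 at a normexp offset of 50 and 0.365 without background correction. S100a8, Lcn2 and Retnlg rose over all genes, and adjusted over the list alone 6 genes were higher and 1 lower. S100a8 went from 8.46 ± 0.71 to 10.6 ± 0.52 (SD, n = 3), and its partner S100a9 from 6.69 ± 0.99 to 8.79 ± 0.58, a difference of 2.09 (limma, adjusted p = 0.0509). The members did not all go one way: 4 of the 11 had a negative fold change. With the 3 genes that no PBS array measured above background set to their bound, the median was 0.86. List means were 0.23, 0.029 and −0.26 in the PBS arrays and 1.18, 0.82 and 0.56 in the DT arrays.

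**Figure D3:**
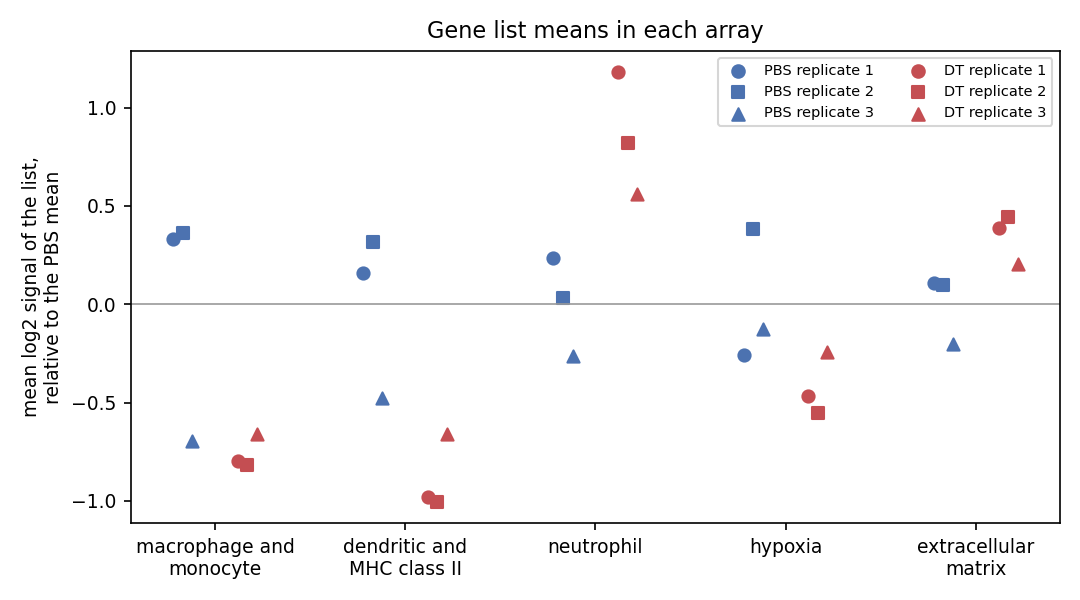
Mean log2 signal of 5 gene lists in each array relative to the PBS mean (y axis), by list (x axis), with PBS arrays in blue, DT arrays in red and a marker shape per replicate number. The macrophage and monocyte list of PBS replicate 3 lies at −0.69, beside the DT arrays, while the neutrophil list of the DT arrays lies between 0.56 and 1.18.

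Genes of the response to hypoxia and of glycolysis were lower in DT. The hypoxia list had a median of −0.40 over 22 measured genes, 18 of them negative (camera adjusted p = 0.00215; adjusted p = 0.806 with an estimated correlation). Ankrd37, a target of the hypoxia-inducible factor, gave −1.58 (SE 0.33), the glycogen branching enzyme Gbe1 −0.83 (SE 0.19), the prolyl hydroxylases P4ha2 and Egln3 −0.995 (SE 0.27) and −0.76 (SE 0.22). None of the 22 passed over all genes in limma, 9 had an unadjusted p under 0.05, and 5 were lower when adjusted over the list alone. The glycolysis list had a median of −0.43 over 13 measured genes, 12 of them negative (camera adjusted p = 0.004; adjusted p = 0.806 with an estimated correlation). Its glucose transporter Slc2a1 gave −0.997 (SE 0.31), Pfkl, a subunit of phosphofructokinase, −0.93 (SE 0.27), Aldoa −0.63 (SE 0.24) and Tpi1 −0.43 (SE 0.16). None of the 13 passed in limma over all genes or over the list alone, and 7 had an unadjusted p under 0.05. PBS replicate 2 was the highest array for both lists, and without it both calls were lost, with medians of −0.18 and −0.28 and an adjusted p of 0.105 for each. With scaling to a common median both lists passed, but the medians were smaller, at −0.23 for hypoxia and −0.20 for glycolysis.

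Genes of oxidative phosphorylation were slightly higher in DT, with a median of 0.18 over 34 measured genes (camera adjusted p = 0.0298; adjusted p = 0.806 with an estimated correlation). Sdhd, a subunit of succinate dehydrogenase, rose by 0.78 (SE 0.15), while Uqcrq, a subunit of the cytochrome bc complex, fell by 0.96 (SE 0.17). The same counts, 1 higher and 1 lower, held when adjusted over the list alone. Atp5c1, of the ATP synthase, gave 0.50 (SE 0.17) and Ndufa4 0.40 (SE 0.15). Without PBS replicate 1 the median was 0.15 and the list did not pass (adjusted p = 0.162). The size also moved with the normalization. It was 0.26 with the deposited normalized values and 0.41 with scaling to a common median, where the median over all genes was 0.165.

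Extracellular matrix genes rose, with a median of 0.33 over 22 measured genes, 17 of them positive (camera adjusted p = 0.00776; adjusted p = 0.806 with an estimated correlation). Col5a2 rose from 5.75 ± 0.51 to 7.33 ± 0.54 (SD, n = 3) and was the 1 gene past the threshold over all genes, and 2 were higher when adjusted over the list alone. The proteoglycan Sdc1, above background on 2 of the 3 PBS arrays, gave 1.23 (SE 0.27), the collagen VI chain Col6a2 0.57 (SE 0.21) and the laminin chain Lamc1 0.43 (SE 0.19). Without PBS replicate 3 the median was 0.21 and the list did not pass (adjusted p = 0.106). Stellate cell and fibroblast markers, which mark the matrix-producing cells of the liver, had a median of 0.21 over 12 measured genes and did not pass (camera adjusted p = 0.132). With no filter on dim probes their median was 0.0393 over 22 genes (adjusted p = 0.1457). They passed without PBS replicate 1 (median 0.27, adjusted p = 0.0114) or without DT replicate 2 (median 0.27, adjusted p = 0.0499). Mfap4 gave 1.27 (SE 0.34) and the collagen III chain Col3a1, already bright at 13.0 in PBS, 0.56 (SE 0.18). None of the 12 passed over all genes in limma, 3 had an unadjusted p under 0.05, and 1 was higher when adjusted over the list alone.

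**Figure D4:**
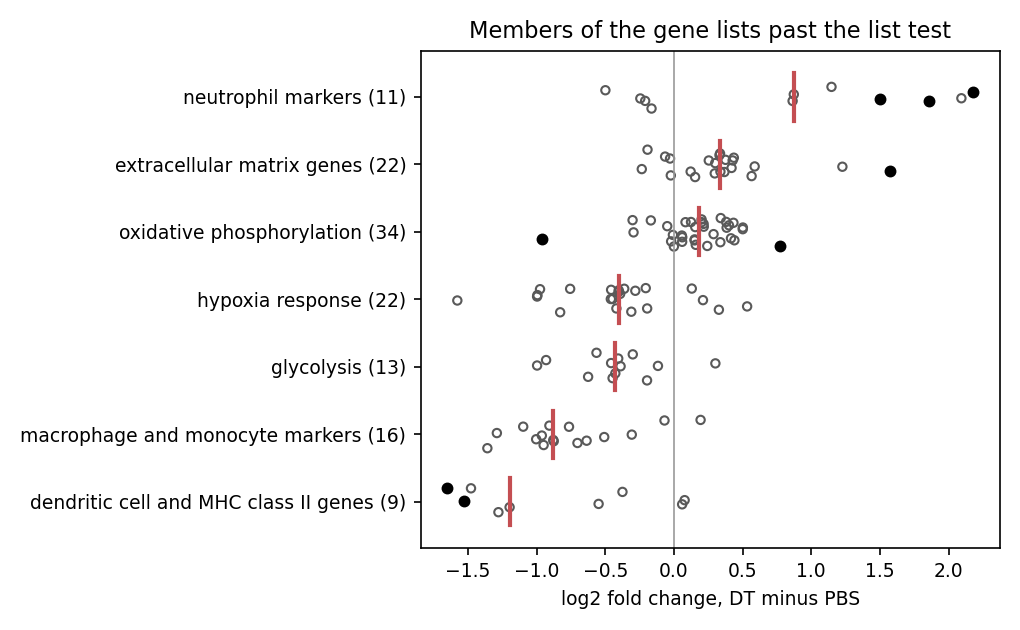
Log2 fold change (x axis, DT minus PBS) of each measured member of the 7 gene lists past the list test (y axis, with the number of measured members), filled where the gene passed an adjusted p of 0.05 over all genes, with the list median as a red bar. Medians run from −1.20 for dendritic cell and MHC class II genes to 0.87 for neutrophil markers.

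Markers of the other cell types that a sort from liver could hold did not pass the list test. T and NK cell markers had a median of −0.38 over 6 genes (camera adjusted p = 0.198). The probe annotated to Prf1, the pore-forming protein of cytotoxic cells, fell from 12.9 ± 0.27 to 11.8 ± 0.37 (SD, n = 3; limma, adjusted p = 0.0459), a high signal for sorted tumour cells, and whether it measures Prf1 alone was not tested. Nkg7 gave −0.67 (SE 0.23), and 2 genes were lower when adjusted over the list alone. Without PBS replicate 3 this list passed, with a median of −0.62 and an adjusted p of 0.0228. Endothelial markers had a median of −0.23 over 6 genes (camera adjusted p = 0.732), which was −0.059 without PBS replicate 2 and 0.015 over 24 genes with no filter. The receptor partner Ramp2 rose by 1.14 (SE 0.21), the VEGF receptor Flt1 gave −0.55 (SE 0.15), and adjusted over the list alone 1 was higher and 2 lower. Hepatocyte markers had a median of 0.028 over 7 genes (camera adjusted p = 0.763), with 0.68 (SE 0.22) for Apoa2 and −0.60 (SE 0.25) for Arg1. Cholangiocyte and epithelial markers had a median of −0.043 over 8 genes (camera adjusted p = 0.773), with −0.31 (SE 0.18) for Sox9 and 0.17 (SE 0.21) for Cdh1, which lay above background on 1 of the 3 PBS and 2 of the 3 DT arrays. Neither list had a gene past the threshold in limma over all genes or over the list alone, and 2 hepatocyte genes and 0 epithelial genes had an unadjusted p under 0.05. Too few genes were measured to test the erythroid list, where Fech gave 0.78 (SE 0.17) and Hba-a1 −0.69 (SE 0.34) among 4 genes, and the platelet list, where Pf4 gave −0.81 (SE 0.21) and Itga2b −0.47 (SE 0.20) among 3. Adjusted over the list alone, 1 erythroid gene was higher and 1 platelet gene lower. No B or plasma cell marker was measured above the filter.

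Among immune and signalling lists, that of angiogenic factors held a single gene past the threshold over all genes: Vegfd, a lymphangiogenic growth factor, rose from 8.45 ± 0.18 to 9.25 ± 0.14 (SD, n = 3; limma, adjusted p = 0.0482). Its relative Vegfc gave 0.62 (SE 0.14), the median of the 25 genes was 0.12 (camera adjusted p = 0.402), and adjusted over the list alone 2 were higher and 1 lower. Of 38 interferon response genes, 9 had an unadjusted p under 0.05 and none passed in limma over all genes or over the list alone (median −0.10, camera adjusted p = 0.475), with 0.56 (SE 0.16) for Ifit2 and −0.44 (SE 0.15) for Irgm1. Without DT replicate 3 this list passed, with a median of −0.19 and an adjusted p of 0.0496. MHC class I antigen presentation genes had a median of 0.15 over 17 genes (camera adjusted p = 0.167), with 0.72 (SE 0.17) for the chaperone Tapbp and 0.67 (SE 0.17) for the proteasome activator Psme2, both higher when adjusted over the list alone. Immune checkpoint and recognition ligands had a median of −0.076 over 10 genes (camera adjusted p = 0.77), with 0.60 (SE 0.15) for Cd47, the ligand that restrains phagocytosis, and 0.49 (SE 0.14) for Cd276, and 2 were higher when adjusted over the list alone. The median of 26 NF-kB targets and inflammatory cytokines was 0.0011 (camera adjusted p = 0.475). Il1b gave −1.52 (SE 0.34) and the chemokine Ccl7 0.68 (SE 0.18), and adjusted over the list alone 1 was higher and 1 lower. TGF-beta and SMAD targets had a median of 0.11 over 19 genes (camera adjusted p = 0.588), with −0.85 (SE 0.25) for Id2 and −0.61 (SE 0.19) for Tgfbi. Mesenchymal and invasion genes had a median of −0.026 over 27 genes (camera adjusted p = 0.763), with −0.82 (SE 0.20) for the matrix protein Tnc and 0.59 (SE 0.19) for Sparc. None of these 19 and 27 genes passed in limma over all genes or over the list alone, and 6 and 7 had an unadjusted p under 0.05. Wnt and intestinal stem cell genes had a median of 0.083 over 10 genes (camera adjusted p = 0.822), with −0.52 (SE 0.18) for Ccnd1 and 0.48 (SE 0.18) for Myc, which lay above background on 1 of the 3 PBS arrays. None passed in limma over all genes or the list alone, and 2 had an unadjusted p under 0.05.

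Growth and stress lists did not pass either. Mitosis genes had a median of −0.049 over 23 genes (camera adjusted p = 0.475), with −0.95 (SE 0.22) for the topoisomerase Top2a and 0.46 (SE 0.18) for the kinesin Kif11. DNA replication genes had a median of −0.063 over 32 genes (camera adjusted p = 0.293), with −0.91 (SE 0.20) for Rpa2 and −0.86 (SE 0.19) for the polymerase subunit Pold1. Adjusted over the list alone, 1 mitosis and 2 replication genes were lower. The list of p53 targets and apoptosis had a median of −0.021 over 21 genes (camera adjusted p = 0.475), with −1.22 (SE 0.31) for the cell cycle inhibitor Cdkn1a and −0.61 (SE 0.17) for Gtse1, and 3 were lower when adjusted over the list alone. ER stress and amino acid response genes had a median of −0.13 over 27 genes (camera adjusted p = 0.205), with −1.14 (SE 0.25) for Trib3 and −0.65 (SE 0.19) for Fgf21. Oxidative stress (NRF2) genes had a median of −0.086 over 21 genes (camera adjusted p = 0.402), with −0.61 (SE 0.14) for the transketolase Tkt and −1.18 (SE 0.45) for the heme oxygenase Hmox1. In each of the ER stress and NRF2 lists, 1 gene was lower when adjusted over the list alone.

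In the sterol synthesis list, with a median of −0.12 over 15 genes (camera adjusted p = 0.475), the cholesterol transfer protein Stard4 fell by 0.90 (SE 0.17) and was the 1 gene past the threshold over all genes and over the list alone, and Sqle gave −0.45 (SE 0.14). Cytosolic ribosomal proteins had a median of 0.082 over 47 genes (camera adjusted p = 0.133), with 0.43 (SE 0.14) for Rpl7a and 0.54 (SE 0.18) for Rpl22. None passed in limma over all genes or over the list alone, 4 had an unadjusted p under 0.05, and the list passed without DT replicate 3 (median 0.12, adjusted p = 0.0496). Translation elongation and diphtheria toxin target genes had a median of −0.11 over 16 genes (camera adjusted p = 0.722), with −0.72 (SE 0.17) for Eif4ebp1, lower when adjusted over the list alone, and 0.37 (SE 0.17) for Eef1b2. Immediate early and heat shock genes went both ways: Hspa1a fell, while the transcription factor Fos rose from 12.7 ± 0.12 to 13.4 ± 0.095 (SD, n = 3; limma, adjusted p = 0.0482). Adjusted over the list alone, 3 of its 28 genes were higher and 2 lower, with a median of −0.037 (camera adjusted p = 0.872). The median and the direction of the list test differed in sign for the immediate early, checkpoint, Wnt and NF-kB lists, and the median and the mean differed for the last 3 of these.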

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

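All tests of the macrophage, neutrophil and fibroblast explanations were chosen after the results were seen. The clock test was chosen, with its genes, after the fall of Dbp but before the values of the other clock genes were seen (Nr1d1 was then added to the report), and the counts over other splits of the arrays were chosen beforehand.

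Probes with no gene named here also carried signal. When every probe was tested with limma, 5 of them were higher and 37 lower in DT past an adjusted p of 0.05, of 2856 such probes above background.

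In camera with the preset correlation the macrophage and the MHC class II lists were lower and the neutrophil list higher in DT (adjusted p = 0.806 for each with an estimated correlation), with 0 of 16, 2 of 9 and 3 of 11 genes past the threshold in limma over all genes (11, 6 and 8 at an unadjusted p under 0.05). A smaller share of all non-tumour cells in the DT sorts would lower every marker list and stays open: the neutrophil list had a median of 0.872 (SE 0.302), but 0.232 (SE 0.187) with no filter on dim probes. These SEs are those of a mean over the member genes, not from limma, and do not measure the spread between samples. Fewer macrophages in the DT sorts are a candidate explanation: of 23 measured macrophage genes outside the lists 87% (20 of 23, median −0.549) were lower, with 28 of 35 (median −0.29) with no filter, and from 19 (median −0.348, without PBS replicate 2) to 21 (median −0.872, without PBS replicate 3) with 1 array left out. Clec7a (−1.22) passed the threshold in limma. The brightest, Slc11a1, gave −0.78 from a PBS mean of 12.9, above Laptm5 at 10.2, and the source of its signal was not tested. These genes come from the same arrays as the lists and are not separate support. PBS replicate 3 lay below the mean of the other PBS arrays in all of them but Wfdc17 and Pla2g7. In most of the genes lower in DT that gap was larger than the DT difference, as in Mpeg1 (−1.07 against −0.42) and Cd53 (−1.43 against −0.62). Apart from Wfdc17, it was smaller only in Clec7a (−0.846 against −1.22), Clec4n (−0.651 against −0.83), Fcgr1 (−0.25 against −0.63) and Slc11a1 (−0.514 against −0.78). For most of these genes the spread within PBS thus exceeded the difference between the groups. More neutrophils stay open, since 63.6% of the measured neutrophil genes (7 of 11) were higher. The sort for MC38 cells should remove both cell types, and a response of the tumour cells themselves was not tested.

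Angptl7, Islr, Omd, Aspn, Dpt and Ccl11 rose by a median of 1.82, and of the 6 calls 5 held without PBS replicate 1 (median 1.98), 3 with the replicate block (1.82), 1 without PBS replicate 2 (1.75), PBS replicate 3 (1.84) or DT replicate 1 (1.82), and 0 without DT replicate 2 (1.54), with no filter (1.82) or with the macrophage covariate (1.86), so that calls were lost at folds of similar size. More fibroblasts in the DT sorts stay open: of 44 fibroblast genes 18 were measured, with a median of 0.397 (bootstrap 95% interval 0.167 to 0.795). The 11 with a mean over all arrays under 8 had a median of 0.545 (0.28 to 0.86). But with no filter the 37 under 8, most of which lie near the background, had 0.0677 (−0.0269 to 0.136). These intervals resample genes, not arrays, and do not measure the spread between samples. None of the 11 passed in limma (8 at an unadjusted p under 0.05, of which Osr1 was lower at −0.41, and up to 3 past the threshold under other settings), and their median lay between 0.0677 and 0.821 over 16 planned settings, the lowest with no filter. The sort for MC38 cells should remove fibroblasts, but its gate is not given. The sorted samples hold other fibroblast transcripts at a high level in PBS (Dcn 13.7, Serpinf1 13.4, Pdpn 11.9). If the tumour cells make these, which was not tested, a small share of fibroblasts would not show there. Lum, Dcn, Mfap4 and Fbln1 are also in the stellate cell list, and a change within the tumour cells stays open as well.

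Dbp fell, and a different phase of the circadian clock at collection is a candidate explanation. The 7 other day-phase output genes of the clock had a median of −0.573, with 6 of them lower: Nr1d1 fell by 1.15 (limma, adjusted p = 0.0459, the 1 call among them), Tef gave −1.03, Ciart −0.72, Nr1d2 −0.57 and Per3 −0.49, but Per1 gave −0.057 and Per2 0.046. The opposite-phase genes Arntl and Clock gave 0.27 and −0.028, with a median of 0.122, and with no filter the medians were −0.485 over 9 day-phase and −0.00518 over 3 opposite-phase genes. The limits chosen for this test were met with the filter on dim probes, but both medians narrowly missed them with no filter. The clock was judged with the filter only, whereas the fibroblast explanation had to hold both ways. The median of the day-phase genes stayed between −0.81 and −0.22 over 16 planned settings, with 0 of them past the threshold with the replicate block, scaling to a common median, no filter, the macrophage covariate (−0.966), or without PBS replicate 2, PBS replicate 3, DT replicate 1 or DT replicate 2. Times of collection are not given in the sources used here, and an effect of DT on the clock stays open.

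Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes as the real split, itself, with 103 genes against 0 as the highest of the other splits. For gene lists 4 of the 10 gave as many, with 7 in the real split and 12 as the highest other, in the split that set PBS replicate 1 with DT replicates 1 and 2 against the rest. With 10 splits no share can fall under 0.05.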

How the results depend on the processing

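The macrophage covariate and the unmoderated test of Angptl7 were chosen after the results were seen, and all other settings before. Against 103 genes, limma called 718 with a normexp offset of 50, 558 without background correction, 27 with scaling to a common median, 310 with cyclic loess and 313 with the deposited normalized values. It called 264 with a detection p under 0.01, 772 with an intensity trend, 1059 with array weights, 240 with every probe tested, and 755 at an adjusted p under 0.1. It called 0 with no filter (2942 at an unadjusted p under 0.05, over 19057 genes), 0 in the unmoderated test (1781) and 0 with the macrophage covariate (981). Leaving out 1 array gave from 0 to 389 genes. The cause was not tested, except that the unfiltered test adjusts over more genes, that leaving out an array leaves fewer arrays and that the covariate leaves fewer residual degrees of freedom. The adjustment is not all of it: with no filter the SE of Angptl7 rose from 0.488 to 0.556. Its unadjusted p in limma rose from 0.000311 to 0.00194, at the same log2 change of 2.608. The replicate number as a block gave 30 genes, 27 of them among the 103, and left Angptl7 at 2.608 (adjusted p = 0.0367). The labels do not state whether the numbers pair the samples. Over all genes tested, deviations of same-numbered arrays correlated at −0.1016, −0.1785 and 0.0301, and not every array correlated best with its own number. Such a check cannot exclude a pairing that affects some genes. Angptl7 was higher in DT under every setting run, from 1.756 to 3.025 (adjusted p from 1.846e-09 to 0.347), and from 2.07 to 3.23 with 1 array left out. The lowest of these p-values came with scaling to a common median, where limma gave Angptl7 and Cdh1 the same SE of 0.377. That p therefore rests on a spread shared by genes and does not measure the spread of Angptl7 itself. Angptl7 did not pass with no filter (2.608, adjusted p = 0.118), in the unmoderated test (2.608, adjusted p = 0.243) or with the macrophage covariate (3.025, adjusted p = 0.347). Against 7 gene lists, camera with an estimated correlation gave 0 (0 at an unadjusted p under 0.05), fry 0 for one direction (4 unadjusted) and 12 for either direction, and leaving out 1 array from 5 to 9. Scaling to a common median added the T and NK cell list (−0.2985, adjusted p = 0.0408) and the angiopoietin list (0.3421, adjusted p = 0.00126), and ribosomal proteins passed without background correction (adjusted p = 0.0313) or filter (0.0124). Besides Angptl7, the 30 named genes that passed kept their call in 241 comparisons with other settings and lost it in 59, and kept it in 68 and lost it in 112 with 1 array left out. The 64 that did not pass gained a call in 201 and 29. Of 30 lists tested, 16 had a median of the other sign under at least 1 setting, 12 with scaling to a common median, 6 with no filter and 10 with 1 array left out (the largest of these −0.1499, for NF-kB without PBS replicate 1), and none of the 7 that passed did. The median of the untested platelet list went from −0.4693 to 0.0156 with no filter. A single direction of a named gene turned with 1 array left out: Cdh1 gave −0.001067 without DT replicate 1, and up to 0.3464 with another array left out. A slide block was not run, since the files give no slides. Signal over background limits dim genes, and those near it have folds pulled towards 0 by the offset.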

Other observations

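The test of histone genes was chosen after the results were seen.

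Replication-dependent histone genes made up 25 of the 72 genes that fell. They are transcribed in S phase from gene clusters. The RNA was amplified with an oligo-dT based kit, so that the signals cover only histone transcripts that such priming reaches. What share of them that is was not tested. Of 51 measured, 25 fell and 0 rose in limma, 48 had a negative fold change, and the median was −0.861. All 13 measured H4 genes fell (median −1.01), as did 8 of 12 H2B genes (median −0.927) and 4 of 15 H2A genes (median −0.463), while 0 of 9 H3 genes passed (median −0.609, 6 at an unadjusted p under 0.05). Several H2A and H3 genes were very bright in PBS (H2ac24 14.83, H2ac13 14.75, H3c13 13.06), while the brightest H4 gene, H4c1, stood at 11.7. Whether saturation limited the folds of the brightest probes was not tested, so the families cannot be compared by these counts alone. Only 47 of the 9432 other genes fell (Fisher's exact test, two-sided, odds ratio 191, p = 2.02e-41), a p that treats genes as independent, which near-identical copies able to share probes are not. The group was also noticed among these same calls, so that this p is no separate support for it. The mean of the group relative to PBS was −0.041, −0.025 and 0.067 in the PBS arrays and −0.79, −0.97 and −0.53 in the DT arrays. Its median stayed between −1.01 and −0.697 over 16 planned settings. The number past the threshold went down to 5 with the replicate block and to 1 with scaling to a common median. It was 0 with no filter, without PBS replicate 2, DT replicate 1 or DT replicate 2, and with the macrophage covariate (median −0.877). The mitosis and DNA replication lists had medians of −0.049 and −0.063 and did not pass.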
